A study of Homo sapiens with 12 samples.

How the data were processed

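RNA was measured by sequencing in 12 libraries of A549 cells, a human lung adenocarcinoma line with alveolar epithelial features. Per the labels' protocols, total RNA was isolated with a NucleoSpin RNA II kit 24 hours after siRNA transfection, only RNA with an integrity number above 7 was sequenced, and libraries followed the standard BGISEQ-500 procedure. Strandedness and removal of ribosomal RNA were not given in the sources used here. The 3 groups of 4 libraries were cells with a non-targeting control siRNA (siCo) and cells with either of 2 siRNA combinations against YAP1 and WWTR1 (the gene of TAZ), called siYAP/TAZ#1 and siYAP/TAZ#2. The series describes the 4 libraries of a group as biological replicates. Groups and replicate numbers were taken from the sample titles.

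Each library had 2 deposited tables, which list the same 60617 Ensembl gene identifiers. The first holds estimated counts, which the authors deposited without further scaling. The second holds the authors' TPM values, deposited as such and with nearly the same sum in every library. The submitters' processing notes name Trim Galore 0.6.4, kallisto 0.4.6 and the genome build GRCh38.p13, with no role or order, and how transcripts were summed to genes was not given in the sources used here. Of the identifiers, 58444 were found in GENCODE v29 and 60357 in a table of gene names. A gene was called lncRNA where GENCODE v29 lists it as a long non-coding RNA, which gave 15904 genes. Coordinates are those of GENCODE v29 on GRCh38, 1-based. Genes known only by a clone name were treated as having no symbol.

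Library totals of estimated counts ran from 29.6 to 38.3 (in units of 1e6). A count of 10 corresponded to 0.25 to 0.375 CPM, which sets how well low genes could be measured. Within groups, Pearson correlations of log2 CPM between libraries ran from 0.979 to 0.991. A chi-square per degree of freedom of 3.68 to 77.5 between libraries of a group was above sampling noise for every pair. That cannot tell biological replicates from libraries of the same RNA, since library preparation also adds spread. All 12 were kept as separate replicates, as the series describes them.

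Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with its defaults, a model with group as its only term over all 12 libraries, and the quasi-likelihood F test. Benjamini-Hochberg adjustment ran over the 21581 genes kept, of which 14805 were protein coding and 4792 lncRNA genes. A gene was called changed at an adjusted p under 0.05, with no minimum fold change. The comparisons were each combination against siCo and the combinations against each other, where the controls cancel, so that the last is also the test of a difference between the effects. Levels are CPM after TMM scaling, as mean ± SD over 4 libraries, and fold changes are log2 values ± standard error. The biological coefficient of variation was 0.105. YAP1 and WWTR1 were also compared by a two-sided exact permutation test of log2 CPM.

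In all, 42 gene lists were fixed before the data were examined, and 79 of their 970 members stood in more than 1 list. Lists were tested against all other genes with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, again with an estimated correlation, and by fry, which asks whether members move on balance one way without comparing them with other genes. List p-values were adjusted over the 42 lists within each comparison. Members called are counted over all genes tested and, in those words, adjusted over the list alone.

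The genes named follow a rule that was also fixed beforehand. It took YAP1 and WWTR1; the 10 coding genes that rose and the 10 that fell most with both combinations, judged by the smaller of the 2 changes, with no overlap between treated and siCo libraries and a mean of at least 5 CPM in a group; 8 lncRNA genes per direction likewise at 1 CPM or more; the 8 genes most different between the combinations in each direction; for each list up to 4 members by adjusted p in the mean of both combinations, of which 1 to 4 appear in the text; and all members of a list of known lncRNAs called with both combinations. The rule took 208 genes. The text names 142 of them, 2 genes that the rule requires are withheld and not reported here, and which list members appear was chosen after their values were seen.

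Because both comparisons use the same siCo libraries, all 12 libraries were simulated with no effect, from the mean of each gene over all libraries. Genes were drawn independently, so trends across genes, such as those with GC content, were left out of the simulated agreement. The siCo libraries were also split between the comparisons. Data were simulated with 200 changed genes of known fold among 21581, all 200 with a mean count of at least 50. Recovery of lower genes was not measured, and the median lncRNA gene tested stood at 0.692 CPM, below that count. On these data the edgeR step for siYAP/TAZ#1 against siCo recovered 57 of 67 genes changed 1.5-fold, 66 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 7 false calls. For siYAP/TAZ#2 against siCo it recovered 29 of 34, 33 of 33 and 33 of 33, with 0 false calls, and for the direct comparison 25 of 33, 31 of 34 and 33 of 33, with 9 false calls. Simulated for siYAP/TAZ#1 against siCo, camera called the 1 changed list and 0 of 40 unchanged lists. Genes were drawn independently here too, so this does not test lists whose members vary together. In the real data the mitosis list had an estimated correlation of 0.402 with siYAP/TAZ#1.

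Alternatives fixed beforehand were DESeq2 1.42.0, DESeq2 size factors within edgeR, no filter or a mean count of at least 50, an absolute log2 change of at least 1, a replicate block, gene length offsets from the ratio of count to TPM, each comparison in its own model, limma on log2(TPM + 1) and log2(TPM + 0.1), lncRNA genes by symbol pattern, and leaving out each library. Added after the data were seen were library size with no TMM factors, offsets for transcript GC content, TPM after TMM factors, and a count over genes without 3 sequence words. Scripts used Python 3.11.15. Raw reads and transcript-level values were not used here. Levels of sex-linked marker genes are not reported.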

Results

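Gene expression was measured by RNA sequencing in A549 lung adenocarcinoma cells, 24 hours after transfection with a control siRNA (siCo) or with either of 2 siRNA combinations directed at YAP and TAZ, the transcriptional coactivators that the Hippo kinase pathway restrains. Each of the 3 groups had 4 libraries, described as biological replicates, with library totals given under data processing. After a filter on low counts, 21581 genes were tested, among them 14805 coding and 4792 lncRNA genes. Throughout, levels are CPM after TMM scaling given as mean ± SD over n = 4 libraries, changes are log2 values ± standard error, and adjusted p comes from edgeR's quasi-likelihood test.

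The first question was whether the targets were depleted in every treated library. YAP1 (ENSG00000137693, chromosome 11, 102110461 to 102233423, plus strand) stood at 121 ± 4.03 CPM in siCo and at 18.7 ± 1.43 and 17.4 ± 1.19 CPM with siYAP/TAZ#1 and siYAP/TAZ#2, which left 15.5% and 14.3%. WWTR1 (ENSG00000018408, chromosome 3, 149517235 to 149736714, minus strand), which encodes TAZ, fell from 241 ± 9.71 to 32.9 ± 1.14 and 32.4 ± 2.38 CPM, leaving 13.7% and 13.5%. All 8 treated libraries lay below all 4 siCo libraries for both genes. The log2 changes were -2.69 ± 0.069 and -2.80 ± 0.070 for YAP1 (adjusted p = 1.91e-13 and 1.43e-13), and -2.87 ± 0.064 and -2.89 ± 0.064 for WWTR1 (adjusted p = 6.20e-14 and 1.16e-13). A two-sided exact permutation test gave p = 0.0286 for each gene and combination, the smallest that 4 against 4 libraries allow. Between the combinations, YAP1 differed by 0.11 ± 0.069 (adjusted p = 0.37) and WWTR1 by 0.02 ± 0.062 (adjusted p = 0.90).

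**Figure D1:**
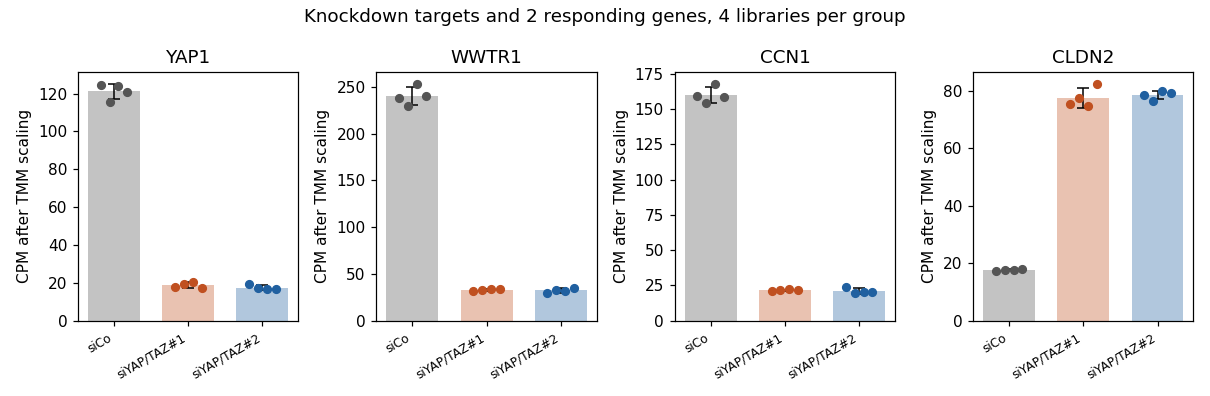
Levels of YAP1, WWTR1, CCN1 and CLDN2 in CPM after TMM scaling (vertical axes) for siCo, siYAP/TAZ#1 and siYAP/TAZ#2. Points are the 4 libraries of a group, bars their mean and error bars the SD; YAP1, WWTR1 and CCN1 lay lower and CLDN2 higher in all treated than in all siCo libraries.

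The second question was what siYAP/TAZ#1 changed against siCo. The secreted matricellular proteins CCN1 and CCN2, textbook YAP/TAZ targets, fell from 160.1 ± 5.8 to 21.4 ± 0.589 CPM and from 22.7 ± 0.998 to 2.71 ± 0.714 CPM. The angiomotin AMOTL2, itself a YAP target and inhibitor, fell from 361 ± 22.8 to 78.2 ± 6.18 CPM, and the growth factor TGFB2 from 133 ± 5.07 to 27.9 ± 1.56. Among genes that rose, the tight junction genes CLDN2 and TJP3 went from 17.7 ± 0.209 to 77.6 ± 3.47 and from 1.04 ± 0.289 to 7.55 ± 1.04 CPM, and BMF, a pro-apoptotic BCL2 family gene, from 2.04 ± 0.301 to 12.6 ± 1.26. In all, 3999 genes were lower and 3531 higher at adjusted p under 0.05, and 317 and 850 of them at an absolute log2 change of at least 1. The split depended on scaling: higher genes made up 46.9% of calls after TMM scaling, 75.5% with library size alone (1905 lower and 5876 higher) and 91.8% on the deposited TPM values (156 lower and 1736 higher).

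For siYAP/TAZ#2 the same question gave a response of similar size. CCN1 fell to 21.1 ± 2.04 CPM (-2.92 ± 0.069), CCN2 to 4.5 ± 0.906 (-2.33 ± 0.15), AMOTL2 to 58.2 ± 10.9 (-2.63 ± 0.11) and TGFB2 to 47.5 ± 2.61 CPM (-1.49 ± 0.060). CLDN2 rose to 78.6 ± 1.46 CPM (2.15 ± 0.054), TJP3 to 6.41 ± 0.936 (2.64 ± 0.18) and BMF to 8.81 ± 0.76 (2.12 ± 0.12). The oncogene MYC fell from 297 ± 9.32 to 122 ± 19.1 CPM and cyclin D1 (CCND1) from 759 ± 21.9 to 325 ± 34.6. In all, 4144 genes were lower and 4100 higher, 403 and 1078 of them at an absolute log2 change of at least 1. Higher genes made up 49.7% of calls after TMM scaling, 76.2% with library size alone (2037 lower and 6538 higher) and 94.7% on TPM (198 lower and 3519 higher). Without TMM factors the median change of all genes moved from 0.02 to 0.20 with siYAP/TAZ#1 and to 0.21 with siYAP/TAZ#2, and all changes here are relative to the TMM scale. The TMM factors were 0.887 to 0.944 in the siCo libraries and 0.967 or above in the treated ones, and a single gene, MIR663AHG, took 3.83% to 5.56% of counts in siCo and 2.18% to 5.21% in treated libraries.

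With 2 combinations against the same targets, the third question was which genes changed with both. Among coding genes the largest common decreases, by the rule for named genes, were YAP1 and WWTR1 themselves with CCN1, CCN2, ANKRD1, AMOTL2, LY6K, the AP-1 subunit FOSL1, the lymphangiogenic factor CCBE1 and GADD45B. ANKRD1, a cardiac ankyrin repeat gene and YAP target, fell from 8.72 ± 0.522 to 1.5 ± 0.297 and 1.15 ± 0.135 CPM, and FOSL1 from 120.0 ± 12.4 to 26.5 ± 1.59 and 24.4 ± 4.67. LY6K (-2.48 and -2.22), CCBE1 (-3.01 and -2.03) and GADD45B (-1.99 and -2.21) are given as log2 changes. The largest common increases were TTBK1, a brain kinase near 0 CPM in siCo (0.141 to 2.45 and 7.01 CPM), SULT1A4, the small GTPase RAB39B (0.487 to 3.08 and 5.26) and TJP3. Next came the phosphatase PTP4A3 (2.43 to 12.1 and 12.3), CEND1, the bradykinin receptor BDKRB2 (4.81 to 21.3 and 30.9), CLDN2, BMF and NACAD. CEND1 rose by 2.19 and 3.26. SULT1A4 rose by 3.22 and 3.37, but it has a near-identical copy among the sulfotransferase genes, so its value is uncertain.

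Both combinations lowered 2867 genes and raised 2693, while 149 genes were called in opposite directions. The split between lower and higher again turned on scaling, with 1134 lower and 4631 higher with library size alone and 70 and 1387 on log2(TPM + 1). Both comparisons use the same siCo libraries. When all 12 libraries were simulated with no effect, the comparisons shared 0.05 calls on average. Genes were drawn independently there, without trends such as those with GC content, so the simulated agreement may be too low. Across genes, which are not independent replicates, the log2 changes correlated at Pearson r = 0.787 against 0.509 in the simulation, had the same sign in 80.3% of genes against 66.9%, and had a covariance of 0.241 against 0.0356, a difference of 0.205. With the siCo libraries split between the comparisons, 1978 to 2063 genes were lower and 1786 to 1826 higher with both, and r was 0.55 to 0.572. The 149 genes in opposite directions were the least stable count. It was 311 without siYAP/TAZ#2 replicate 1, 299 with GC offsets, 73 with gene length offsets, 59 among genes without 3 sequence words, 1 on log2(TPM + 1) and 0 at an absolute log2 change of at least 1.

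**Figure D2:**
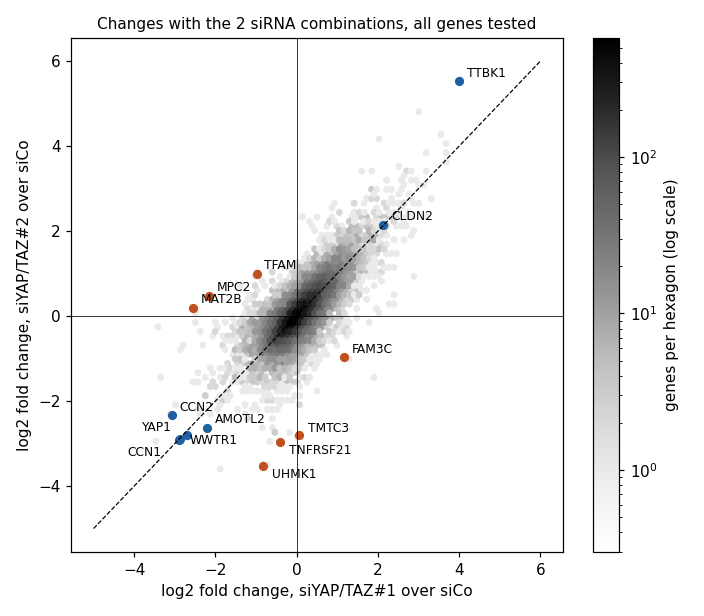
Log2 fold change over siCo with siYAP/TAZ#1 (horizontal axis) and siYAP/TAZ#2 (vertical axis) for the 21581 genes tested; shading counts genes per hexagon on a log scale and the dashed line marks equal change. Blue points are genes that changed in the same direction, such as CCN1 (-2.90 and -2.92), and orange points genes among the most different or called in opposite directions, such as TMTC3 (0.05 and -2.81).

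Gene groups were compared with all other genes in both comparisons, and values are given for siYAP/TAZ#1 first. Target genes of YAP/TAZ had the lowest camera p of all lists. Of 22 genes of a YAP/TAZ target signature, 22 and 22 fell and 0 rose (the same adjusted over the list alone, and 21 and 19 fell and 0 rose with library size alone) (camera adjusted p = 6.36e-55 and 7.37e-34; adjusted p = 7.04e-05 and 4.95e-04 with an estimated correlation). They include the receptor kinase AXL, which fell from 1175 ± 35.3 to 569 ± 35 and 536 ± 57.4 CPM. Of 55 measured genes of a conserved YAP signature, 32 and 33 fell and 4 and 6 rose (33 and 35 fell and 4 and 7 rose adjusted over the list alone, and 24 and 25 fell and 8 and 11 rose with library size alone). Its adjusted p = 0.0054 and 0.0083 with an estimated correlation. Of 30 Hippo pathway components and TEAD factors, 14 and 17 fell and 3 and 3 rose (6 and 4 rose adjusted over the list alone, and 11 and 15 fell and 8 and 6 rose with library size alone). The list had adjusted p = 0.0054 and 0.0023 with an estimated correlation. Among them the tumour suppressor NF2 fell from 355 ± 16.7 to 187 ± 11 and 142 ± 10.9 CPM, and FRMD6 from 47.2 ± 0.667 to 16.5 ± 1.29 and 21.7 ± 0.365.

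Genes of DNA synthesis and ribosome production fell together. Of 40 DNA replication genes, 28 and 33 fell and 0 rose (33 and 33 fell adjusted over the list alone, and 11 and 19 fell and 0 and 2 rose with library size alone), with adjusted p = 0.018 and 0.020 with an estimated correlation. They were led by the GINS subunit GINS1 (-1.49 and -0.71), the methylation factor UHRF1 (-1.46 and -1.10), the helicase factor CDC45 (-0.53 and -1.07) and MCM10 (-0.67 and -0.69). Of 27 ribosome biogenesis genes, 25 and 25 fell and 0 rose (26 and 26 fell adjusted over the list alone, and 20 and 21 fell and 0 rose with library size alone), among them the nucleolar proteins NOLC1 (-0.92 and -0.96) and DKC1 (-0.77 and -0.95). That list had adjusted p = 0.0054 and 0.0083 with an estimated correlation. Of 22 MYC target genes, 21 and 21 fell and 0 rose (the same adjusted over the list alone, and 14 and 14 fell and 0 rose with library size alone), with adjusted p = 0.0064 and 0.0083 with an estimated correlation. The nucleoside kinase NME1 (-1.15 and -0.45) and the chaperone FKBP4 (-0.80 and -0.79) were among them. Of 36 mitosis genes, 30 and 28 fell and 0 rose (32 and 28 fell adjusted over the list alone, and 17 and 11 fell and 0 rose with library size alone), such as the kinases AURKA (-0.75 and -0.62) and AURKB (-0.49 and -0.54). That list was called at the preset correlation alone, with adjusted p = 0.20 and 0.22 with an estimated correlation. Of 20 G1 cyclins, CDKs and CDK inhibitors, 9 and 10 fell and 3 and 2 rose (10 and 10 fell adjusted over the list alone, and 6 and 7 fell and 5 and 5 rose with library size alone), and the siYAP/TAZ#2 median turned positive with library size alone. The G1 list was called in both comparisons at the preset correlation, with adjusted p = 0.039 and 0.060 with an estimated correlation. CDK2 fell from 70.9 ± 2.31 to 33.9 ± 1.49 and 46 ± 3.89 CPM.

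Detoxification, epithelial and interferon genes moved up. Of 28 NRF2 target genes, which encode antioxidant enzymes, 0 and 3 fell and 21 and 15 rose (23 and 17 rose adjusted over the list alone, and 0 fell and 25 and 21 rose with library size alone). The list had adjusted p = 0.0054 and 0.045 with an estimated correlation. GPX2 rose from 39.2 ± 3.82 to 111 ± 5.29 and 137 ± 4.02 CPM and HMOX1 from 415 ± 2.94 to 965 ± 55.3 and 682 ± 52.1. AKR1C1, which has close paralogs and so an uncertain value, rose by 1.26 and 1.06. Of 24 epithelial genes, 5 and 5 fell and 14 and 14 rose (the same adjusted over the list alone, and 5 and 3 fell and 15 and 16 rose with library size alone). Besides CLDN2 and TJP3, the transcription factor ELF3 (1.16 and 1.01) and plakoglobin, JUP (0.99 and 1.22), rose. Of 13 airway epithelial markers, 2 and 1 fell and 9 and 9 rose (the same adjusted over the list alone, and 1 and 1 fell and 9 and 10 rose with library size alone). The mucin MUC5B stood at 13.5, 33.2 and 55.4 CPM in siCo, siYAP/TAZ#1 and siYAP/TAZ#2, and its regulator SPDEF at 5.7, 21.5 and 19.1. TP63 (2.18 and 2.30), a basal cell factor, belongs to this list as well. Of 32 interferon stimulated genes, 2 and 1 fell and 21 and 20 rose (the same adjusted over the list alone, and 2 and 0 fell and 24 and 24 rose with library size alone), such as IRF9 (1.46 and 1.29) and OAS1 (1.12 and 1.11). The epithelial, airway and interferon lists were called at the preset correlation. With an estimated correlation adjusted p was 0.16 and 0.14, 0.11 and 0.053, and 0.13 and 0.15.

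On the TMM scale, adhesion, cytoskeleton and signalling genes fell in larger numbers than they rose, while with library size alone several of these lists had as many rises or more. Of 32 focal adhesion and integrin genes, 16 and 15 fell and 2 and 4 rose (the same adjusted over the list alone, and 11 and 7 fell and 4 and 9 rose with library size alone), with adjusted p = 0.043 and 0.23 with an estimated correlation. Paxillin, PXN (-0.54 and -0.52), and the integrin subunit ITGAV (-1.05 and -0.19) were among them, the latter with a positive siYAP/TAZ#2 change on TPM without TMM factors. Of 26 receptor tyrosine kinases and ligands, 14 and 17 fell and 6 and 4 rose (15 and 17 fell and 6 and 5 rose adjusted over the list alone, and 9 and 14 fell and 8 and 8 rose with library size alone). The list had adjusted p = 0.13 and 0.030 with an estimated correlation, and EPHA2 fell from 503 ± 24.4 to 177 ± 10.7 and 192 ± 23.6 CPM. Of 27 apoptosis regulators, 12 and 15 fell and 3 and 3 rose (13 and 15 fell and 5 and 3 rose adjusted over the list alone, and 8 and 13 fell and 9 and 4 rose with library size alone), with adjusted p = 0.11 and 0.017 with an estimated correlation. The survival gene MCL1 fell from 207 ± 4.54 to 125 ± 2.69 and 45.6 ± 2.71 CPM while BMF rose. Of 36 actin cytoskeleton genes, 23 and 13 fell and 4 and 4 rose (24 and 13 fell adjusted over the list alone, and 10 and 6 fell and 4 and 8 rose with library size alone), and the siYAP/TAZ#2 median turned positive with library size alone. That list, with TPM1 (-1.03 and -0.88) and TAGLN2 (-2.05 and -0.53), had adjusted p = 0.11 and 0.37 with an estimated correlation. Of 41 extracellular matrix genes, 15 and 17 fell and 8 and 7 rose (16 and 17 fell adjusted over the list alone, and 11 and 15 fell and 15 and 14 rose with library size alone), and both medians turned positive with library size alone. The protease PLAU (-1.41 and -1.01) and fibronectin, FN1 (0.82 and 0.76), belong to it (adjusted p = 0.31 and 0.25 with an estimated correlation). Of 16 mesenchymal genes such as TGFBI (-0.65 and -0.73), 9 and 7 fell and 3 and 4 rose (3 and 5 rose adjusted over the list alone, and 7 and 6 fell and 5 and 6 rose with library size alone), and the siYAP/TAZ#2 median turned positive with library size alone. The mesenchymal list had camera adjusted p = 0.049 and 0.44, and adjusted p = 0.24 and 0.61 with an estimated correlation. Of 22 TGF-beta target genes, 8 and 10 fell and 4 and 2 rose (4 and 3 rose adjusted over the list alone, and 8 and 8 fell and 7 and 6 rose with library size alone), and the siYAP/TAZ#1 median turned positive with library size alone. TGF-beta target genes had adjusted p = 0.24 and 0.25 with an estimated correlation. Of 15 Wnt target genes, 7 and 7 fell and 4 and 2 rose (the same adjusted over the list alone, and 4 and 6 fell and 5 and 3 rose with library size alone), and the siYAP/TAZ#1 median turned positive with library size alone. The Wnt list had camera adjusted p = 0.35 and 0.0073, and adjusted p = 0.64 and 0.23 with an estimated correlation. DKK1 (-0.84 and -1.51) fell and RNF43 (0.85 and 0.42) rose. All other lists of this paragraph but the mesenchymal were called in both comparisons at the preset correlation.

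More inflammatory, early response and nutrient genes fell than rose on the TMM scale, while p53 target genes went both ways. Of 22 NF-kB and cytokine genes, 11 and 11 fell and 4 and 3 rose (12 and 12 fell adjusted over the list alone, and 9 and 10 fell and 6 and 4 rose with library size alone), with IL11 (-2.48 and -1.59) down and PTGS2 (1.01 and 0.88) up. Its values were camera adjusted p = 0.050 and 0.041, and adjusted p = 0.32 and 0.29 with an estimated correlation. Of 24 AP-1 and early genes, 12 and 14 fell and 3 and 2 rose (the same adjusted over the list alone, and 9 and 10 fell and 8 and 6 rose with library size alone), with DUSP1 (-1.04 and -0.90) down and FOS (1.20 and 1.14) up. The AP-1 list had adjusted p = 0.49 and 0.27 with an estimated correlation. Of 29 p53 target genes, 6 and 12 fell and 7 and 11 rose (7 and 12 fell adjusted over the list alone, and 3 and 4 fell and 15 and 13 rose with library size alone), and the siYAP/TAZ#2 median, opposite in sign to its mean, turned positive with library size alone (camera adjusted p = 0.75 and 0.80). PLK2 (-0.86 and -0.88) and AEN (-0.44 and -0.67) fell and cyclin G1, CCNG1 (1.38 and 0.90), rose. Of 23 glycolysis genes such as SLC16A1 (-0.54 and -1.58) and PFKP (-0.72 and -0.72), 11 and 15 fell and 1 and 2 rose (the same adjusted over the list alone, and 6 and 6 fell and 3 and 4 rose with library size alone), and the siYAP/TAZ#1 median turned positive with library size alone. Glycolysis genes had adjusted p = 0.32 and 0.22 with an estimated correlation. Of 23 hypoxia genes such as ADM (-1.67 and -1.91) and STC2 (-1.15 and -1.25), 11 and 11 fell and 4 and 3 rose (12 and 12 fell adjusted over the list alone, and 6 and 8 fell and 5 and 3 rose with library size alone). Hypoxia genes had adjusted p = 0.24 and 0.099 with an estimated correlation. The AP-1, glycolysis and hypoxia lists were called in both comparisons at the preset correlation. Of 18 amino acid transporter and glutamine genes such as SLC7A1 (-0.68 and -1.18) and SLC7A5 (-0.52 and -0.91), 11 and 10 fell and 4 and 2 rose (4 and 3 rose adjusted over the list alone, and 4 and 6 fell and 6 and 5 rose with library size alone). With siYAP/TAZ#1 the mean of that list was positive and its median and test negative (camera adjusted p = 0.19 and 0.0013; adjusted p = 0.28 and 0.030 with an estimated correlation). Of 55 cytosolic ribosomal protein genes, 11 and 28 fell and 0 rose (3 and 28 fell adjusted over the list alone, and 0 and 2 fell and 3 and 1 rose with library size alone), and the siYAP/TAZ#1 median turned positive with library size alone. Ribosomal protein genes had camera adjusted p = 0.069 and 8.24e-04, and adjusted p = 0.64 and 0.43 with an estimated correlation. RPL14 (-0.32 and -0.45) and RPL9 (-0.40 and -0.37) had positive changes on TPM without TMM factors.

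Organelle, lipid and stress genes had no common direction. Of 26 autophagy and lysosome genes such as WIPI1 (0.77 and 1.02) and NEU1 (0.90 and 0.37), 4 and 7 fell and 13 and 10 rose (the same adjusted over the list alone, and 1 and 5 fell and 17 and 17 rose with library size alone). As a list they had camera adjusted p = 0.011 and 0.76, and adjusted p = 0.21 and 0.84 with an estimated correlation. Of 24 cholesterol synthesis genes, 3 and 9 fell and 11 and 3 rose (3 and 10 fell and 12 and 3 rose adjusted over the list alone, and 2 and 4 fell and 17 and 7 rose with library size alone), and the siYAP/TAZ#2 median turned positive with library size alone (camera adjusted p = 0.063 and 0.11). Of 19 fatty acid genes such as ACSS2 (0.83 and 0.59) and ELOVL1 (-0.47 and -0.67), 3 and 3 fell and 9 and 9 rose (the same adjusted over the list alone, and 2 and 1 fell and 10 and 10 rose with library size alone) (camera adjusted p = 0.14 and 0.45). Of 26 stress response genes such as EDEM1 (-1.48 and -0.42) and HSPA5 (-0.80 and -0.13), 7 and 7 fell and 7 and 5 rose (the same adjusted over the list alone, and 3 and 5 fell and 13 and 9 rose with library size alone), with positive medians but negative means and tests (camera adjusted p = 0.59 and 0.46). HSPA5 with siYAP/TAZ#2 turned positive with library size alone and on TPM without TMM factors. Of 34 nuclear oxidative phosphorylation genes, 8 and 8 fell and 0 rose (the same adjusted over the list alone, and 3 and 3 fell and 8 and 4 rose with library size alone), and both medians turned positive with library size alone (camera adjusted p = 0.19 and 0.12). ATP5MC1 (-0.46 and -0.33) fell with both combinations and SDHD with siYAP/TAZ#2 (-0.49). Of 15 RNA interference genes, 8 and 9 fell and 2 and 1 rose (3 and 2 rose adjusted over the list alone, and 2 and 4 fell and 3 and 3 rose with library size alone), and both medians turned positive with library size alone. That list had camera adjusted p = 0.29 and 0.010, and adjusted p = 0.63 and 0.25 with an estimated correlation. DICER1 (-0.41 and -0.88) fell with both combinations and AGO2 with siYAP/TAZ#2 (-0.80). Of 18 histone genes, 3 and 10 fell and 0 rose (2 and 11 fell adjusted over the list alone, and 1 and 2 fell and 0 and 2 rose with library size alone), and the siYAP/TAZ#1 median turned positive with library size alone. Histone genes had camera adjusted p = 0.19 and 0.040, and adjusted p = 0.64 and 0.43 with an estimated correlation. H3-3B (-0.35 and -0.31) fell with both and H2BC4 with siYAP/TAZ#2 (-0.51). Of 13 mitochondrially encoded genes such as MT-ND3 and MT-ATP8, 0 fell and 0 rose (the same adjusted over the list alone, and 0 fell and 3 and 6 rose with library size alone) (camera adjusted p = 0.42 and 0.30).

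Lineage markers gave little. Of 11 alveolar markers, 2 and 2 fell and 3 and 2 rose (4 and 2 rose adjusted over the list alone, and 2 and 2 fell and 6 and 3 rose with library size alone), with positive medians and means but negative tests (camera adjusted p = 0.91 and 0.73). LPCAT1 (-1.17 and -1.24) and CAV1 (-0.60 and -0.66) fell, while 2 other members rose with both combinations. Of 8 fibroblast markers, 0 fell and 2 and 2 rose (the same adjusted over the list alone, and 0 fell and 2 and 3 rose with library size alone) (camera adjusted p = 0.35 and 0.094), with THY1 at 7.69, 10.1 and 18.1 CPM and COL1A1 (0.47 and 0.09). Of 5 blood cell markers, 0 fell and 1 and 1 rose (the same adjusted over the list alone, and 0 fell and 1 and 1 rose with library size alone) (camera adjusted p = 0.35 and 0.23), CD14 rising from 2.23 to 5.76 and 7.07 CPM, while CD68 was not called. Of 3 endothelial markers, 0 fell and 1 and 1 rose (the same adjusted over the list alone, and 0 fell and 2 and 1 rose with library size alone) (camera adjusted p = 0.43 and 0.52), ESAM rising from 3.45 to 4.51 and 4.79 CPM, while PECAM1 was not called. In all, camera called 24 and 28 of 42 lists at the preset correlation and 9 and 11 with an estimated one, and fry called 38 and 38. With 8 libraries per comparison the real groups gave 25 and 26 lists at the preset correlation, and other splits of the same libraries up to 26 and 27. With an estimated correlation the real groups gave 8 and 10, and other splits 0 and 0.

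**Figure D3:**
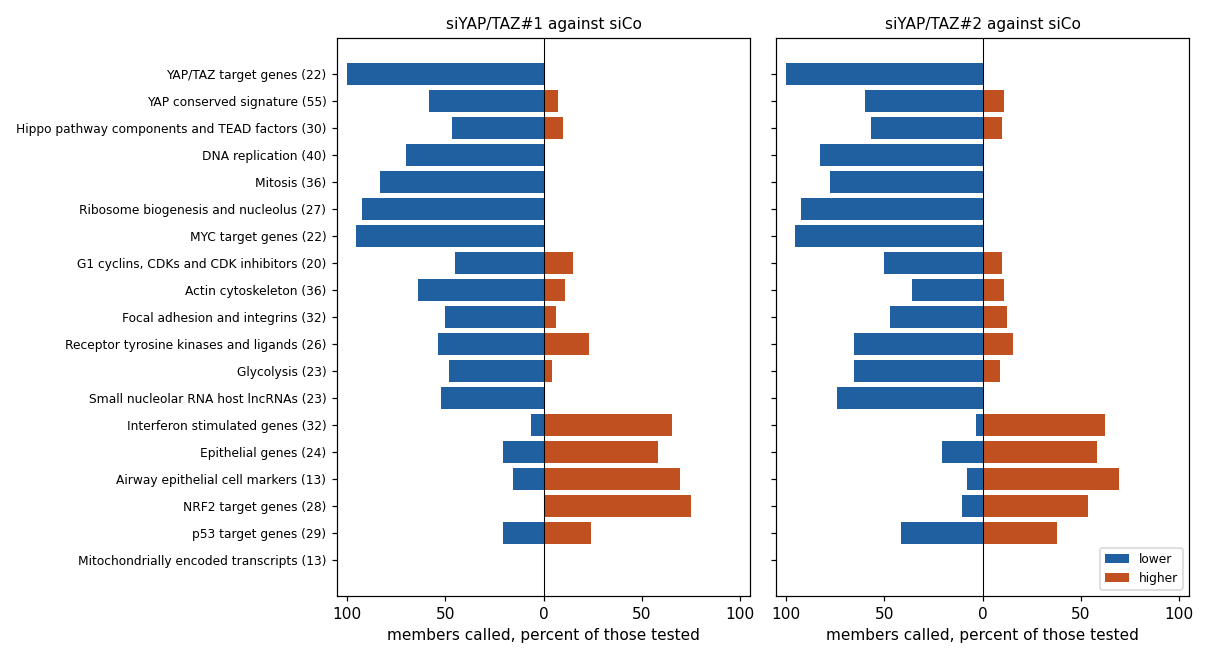
Share of the measured members of 19 gene lists that were called lower (blue, to the left) or higher (orange, to the right) than siCo, in percent of members tested, with the number tested in parentheses. All 22 signature genes of YAP/TAZ lay to the left with both combinations, NRF2 targets mostly to the right, and mitochondrially encoded transcripts had no call. Medians of the G1, actin, glycolysis and p53 lists changed sign in 1 comparison each with library size alone.

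The series asks about lncRNAs, so the same comparisons were made within the 4792 lncRNA genes tested. Among those that fell with both combinations, AFAP1-AS1 went from 6.71 ± 2.74 to 2.5 ± 0.746 and 1.44 ± 0.92 CPM and VPS9D1-AS1 from 62.9 ± 2.64 to 30.1 ± 1.24 and 28.6 ± 2.03. CYTOR fell from 41.1 ± 1.5 to 24.5 ± 0.552 and 19.5 ± 1.79 CPM, and the snoRNA host SNHG15 from 13.9 ± 1.91 to 7.58 ± 1.31 and 5.86 ± 0.572. The microRNA hosts MIR503HG (-0.86 and -0.99) and MIR222HG (-0.76 and -0.83), LINC01783 (-0.92 and -1.40) and PRR7-AS1 (-0.83 and -0.76) fell as well. Among those that rose, SSTR5-AS1 went from 0.793 ± 0.208 to 3.39 ± 0.81 and 2.96 ± 0.993 CPM, and LMNTD2-AS1 from 1.43 ± 0.23 to 3.99 ± 0.247 and 4.46 ± 0.549. LINC00574, LINC01942, LINC01948, INKA2-AS1 and THBS2-AS1 rose from 0.347, 0.417, 0.426, 0.547 and 0.421 CPM to between 1.04 and 1.68 CPM. In all, 150 lncRNA genes were lower and 476 higher with siYAP/TAZ#1, 233 and 477 with siYAP/TAZ#2, and 100 and 296 with both; adjusted over the list alone, 73 and 194 with both. With the siCo libraries split between the comparisons, 61 to 72 were lower and 141 to 151 higher with both.

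In each comparison of the 56 measured members of a list of known lncRNAs, 13 and 18 fell and 10 and 10 rose (13 and 19 fell and 11 and 10 rose adjusted over the list alone, and 10 and 13 fell and 17 and 19 rose with library size alone), with positive medians but negative tests. Of these members, 13 fell and 6 rose with both combinations, and the list was not called (camera adjusted p = 0.52 and 0.074). Besides those above, the host genes MIR4435-2HG (-0.62 and -0.86), MIR17HG (-0.49 and -0.91), SNHG1 (-0.73 and -0.76) and SNHG12 (-0.62 and -0.55) fell. OIP5-AS1, GAS5, MIR22HG, MIR31HG and MEG3 fell from 80.9, 35.6, 25.6, 38.3 and 125 CPM to 39.6, 25.9, 22.2, 31.9 and 94.7 with siYAP/TAZ#1 and 60.0, 24.3, 18.8, 31.1 and 102 with siYAP/TAZ#2. On TPM without TMM factors the changes of these last 5 turned positive, in both comparisons for MIR22HG, MIR31HG and MEG3, with siYAP/TAZ#1 for GAS5 and with siYAP/TAZ#2 for OIP5-AS1. On TPM after TMM factors these changes were not reversed. MALAT1 rose from 2121 ± 59.5 to 2595 ± 175 and 2727 ± 383 CPM, and CASC9 (0.60 and 0.70), PURPL (0.49 and 0.46), TP53TG1 (0.47 and 0.60), LINC01116 (0.44 and 0.41) and TINCR (0.61 and 0.48) rose too. Of 23 snoRNA host lncRNAs, 12 and 17 fell and 0 rose (13 and 17 fell and 1 and 0 rose adjusted over the list alone, and 7 and 11 fell and 2 and 1 rose with library size alone), and the list was called in both comparisons at the preset correlation, with adjusted p = 0.13 and 0.039 with an estimated correlation. SNHG17 fell from 81.5 ± 7.02 to 51.1 ± 1.23 and 40.7 ± 2.39 CPM. Of 21 microRNA host lncRNAs, 8 and 9 fell and 5 and 4 rose (8 and 10 fell adjusted over the list alone, and 5 and 8 fell and 6 and 4 rose with library size alone), and the siYAP/TAZ#1 median turned positive with library size alone. They had camera adjusted p = 0.60 and 0.082. Several antisense genes share exon sequence with a gene on the other strand (AFAP1-AS1 191 bases with AFAP1, VPS9D1-AS1 154 with VPS9D1, LMNTD2-AS1 309 with LMNTD2, PRR7-AS1 99 with GRK6, OIP5-AS1 470 with OIP5, MIR4435-2HG 727 with BCL2L11), and strandedness was not given, so which strand their reads came from is uncertain.

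Of the lncRNA genes called with both combinations, 74.7% rose (95% exact binomial interval 70.2% to 79.0%), against 45.6% of coding genes (44.2% to 47.0%). Coding genes matched to them on mean CPM rose in 81.6% (77.4% to 85.3%), so the lncRNA share lay above that of all coding genes and not above that of equally abundant ones. The intervals take genes as independent, which they are not, and leave out the spread between libraries and the choice of scaling. With library size alone, the lncRNA counts with both combinations were 53 lower and 556 higher. By gene symbol pattern in place of the annotation they were 51 and 168.

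**Figure D4:**
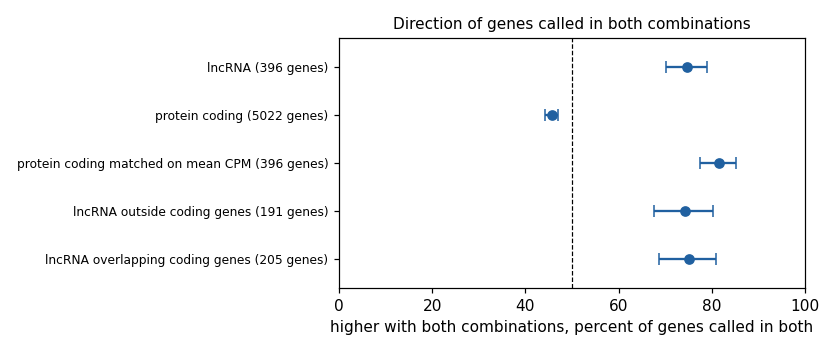
Percent of genes called with both combinations that were higher than siCo (horizontal axis), for lncRNA genes, coding genes, coding genes matched to the lncRNA genes on mean CPM, and lncRNA genes outside and overlapping coding genes. Points are shares and bars 95% exact binomial intervals, which take genes as independent: 74.7% of lncRNA genes, 45.6% of coding genes and 81.6% of matched coding genes.

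The last question was how the combinations differed from each other. The methionine metabolism gene MAT2B stood at 5.07 ± 0.41 CPM with siYAP/TAZ#1 and 33.9 ± 4.55 with siYAP/TAZ#2, against 29.6 ± 0.954 in siCo, and the mitochondrial pyruvate carrier MPC2 at 11.9 ± 1.11 and 73.6 ± 6.58, against 53 ± 3.04. In the other direction TMTC3 stood at 66.5 ± 3.78 and 9.18 ± 1.65 CPM, against 64.4 ± 5.86, the kinase UHMK1 at 99.8 ± 2.68 and 15.3 ± 2.92, against 177 ± 10.4, and the death receptor TNFRSF21 at 169 ± 9.48 and 29.1 ± 2.44, against 226 ± 10.4. Also lower with siYAP/TAZ#1 than with siYAP/TAZ#2 were NACAD (-2.17 ± 0.16), LINC00707 (-2.13 ± 0.13), CNIH1 (-2.08 ± 0.11), MIS18A (-2.08 ± 0.15), GALNT12 (-2.01 ± 0.16) and the mitochondrial DNA factor TFAM (-1.98 ± 0.095). Higher were LYRM1 (2.26 ± 0.096), OSTM1 (2.19 ± 0.073), ARL6IP1 (2.16 ± 0.088), the cell cycle factor E2F5 (2.16 ± 0.085) and FAM3C (2.13 ± 0.11). Of these, MPC2 (-2.16 and 0.47), TFAM (-0.99 and 1.00), GALNT12 (-1.06 and 0.94), LYRM1 (0.45 and -1.81) and FAM3C (1.17 and -0.97) were called in opposite directions against siCo.

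In all, 1769 genes were lower and 1493 higher with siYAP/TAZ#1 than with siYAP/TAZ#2, of them 37 and 97 lncRNA genes (13 and 41 adjusted over the list alone). Among genes without 3 sequence words 881 were higher. Among the lists, camera called 14 at the preset correlation and 0 with an estimated correlation, and fry called 19. Lower with siYAP/TAZ#1 were the YAP/TAZ signature, actin and focal adhesion lists. Higher were the Wnt, receptor kinase, apoptosis, amino acid, NRF2, hypoxia, ribosomal protein, RNA interference, autophagy, snoRNA host and cholesterol lists. Some had few members called, such as 1 of 55 ribosomal protein genes and 3 of 23 snoRNA hosts higher, with 0 lower in each. Other splits of the same libraries gave up to 18 lists at the preset correlation. The cholesterol synthesis list had the lowest camera p: 12 of 24 genes were higher and 3 lower with siYAP/TAZ#1 (17 and 3 adjusted over the list alone; camera adjusted p = 1.80e-06; adjusted p = 0.31 with an estimated correlation). Squalene epoxidase, SQLE, went the other way (-0.58 ± 0.066). Without siYAP/TAZ#2 replicate 1, a library apart from its group, the direct comparison called 2840 lower and 2287 higher genes, of them 62 and 164 lncRNA genes; lncRNA genes higher with siYAP/TAZ#1 numbered 62 and 61 without its replicate 1 or 3. With offsets for GC content 2519 genes were lower and 2515 higher with siYAP/TAZ#1, more in both directions. With offsets for gene length 948 were lower and 901 higher.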

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

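The tests weighed for siYAP/TAZ#2 replicate 1 were chosen after the result was seen, while the test between the combinations was planned. The bound for a swap with a siYAP/TAZ#1 library replaced an earlier one, which asked for a lower quartile above 0.5 and was missed at 0.472. In 28 of 447 groups of 4 libraries (6.26%, against 5% by chance) a single library lay far from the other 3. The CPM values of those libraries were, for siCo replicate 1: PTP4A3 (2.63) and MCM10 (64.1). For siCo replicate 2: MIS18A (11.4) and ACSS2 (30.5). For siCo replicate 3: TP53TG1 (7.01). For siCo replicate 4: CDK2 (74.3), PTGS2 (107), SLC7A5 (5161), VPS9D1-AS1 (59), MIR31HG (34.1), CNIH1 (74.9) and MT-ND3 (11.8). For siYAP/TAZ#1 replicate 2: TTBK1 (3.1), MYC (194) and SLC7A5 (4060.2). For siYAP/TAZ#1 replicate 4: TGFB2 (25.6), CDC45 (23.3) and SNHG12 (12.6). For siYAP/TAZ#2 replicate 1: AKR1C1 (236), SPDEF (25.2), AFAP1-AS1 (2.81), CNIH1 (32), CCNG1 (42.6), PXN (283), RPL9 (30.8) and DICER1 (92). In siYAP/TAZ#1 replicate 2, lncRNA genes other than MIR663AHG held 1.54% of counts. In siYAP/TAZ#2 replicate 1 the deviation from its group had a Spearman correlation of 0.818 with transcript GC content, against -0.688 to -0.617 in the others of its group. Deviations within a group balance out, so its positive trend by itself pushes the values of the others down.

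Of the 142 genes named, 67 differed between the combinations by the edgeR test of siYAP/TAZ#1 against siYAP/TAZ#2, on the log2 scale. Lower with siYAP/TAZ#1 were CCN2 (-0.73), CCBE1 (-0.97), TGFB2 (-0.77), TTBK1 (-1.52), RAB39B (-0.77), CEND1 (-1.06), BDKRB2 (-0.54), NACAD (-2.17), GINS1 (-0.79), UHRF1 (-0.36), CDK2 (-0.44), FRMD6 (-0.39), NME1 (-0.70), GPX2 (-0.30), MUC5B (-0.74), IL11 (-0.88), TAGLN2 (-1.52), PLAU (-0.40), SQLE (-0.58), THY1 (-0.85), ITGAV (-0.86), OIP5-AS1 (-0.60), MAT2B (-2.74), MPC2 (-2.63), LINC00707 (-2.13), CNIH1 (-2.08), MIS18A (-2.08), GALNT12 (-2.01), TFAM (-1.98), EDEM1 (-1.06), HSPA5 (-0.67) and WIPI1 (-0.25). Higher were AMOTL2 (0.43), BMF (0.51), CDC45 (0.54), CCND1 (0.72), NF2 (0.40), MYC (0.59), HMOX1 (0.50), AKR1C1 (0.21), MCL1 (1.45), SLC16A1 (1.04), SLC7A5 (0.39), AGO2 (0.75), DKK1 (0.68), CYTOR (0.33), MIR4435-2HG (0.24), SNHG17 (0.33), TMTC3 (2.85), UHMK1 (2.70), TNFRSF21 (2.54), LYRM1 (2.26), OSTM1 (2.19), ARL6IP1 (2.16), E2F5 (2.16), FAM3C (2.13), MIR22HG (0.24), CCNG1 (0.49), AEN (0.23), RNF43 (0.43), SLC7A1 (0.50), ACSS2 (0.23), ELOVL1 (0.20), SDHD (0.33), DICER1 (0.47), NEU1 (0.52) and COL1A1 (0.38).

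The library siYAP/TAZ#2 replicate 1 stands apart: its deviation from its group had an SD of 0.34, against 0.176 or less elsewhere. A GC trend took 65.7% of that variance (44.0% or less elsewhere), so GC content bias could be part of the cause. The highest values elsewhere, 0.176 and 44.0%, were those of siYAP/TAZ#2 replicate 2, measured against a mean that includes replicate 1. After removal of the GC trend the SD of replicate 1 was still 0.199, against 0.149 or less in the others. That argues against GC as the whole cause. A failed transfection or a swap with a siCo library is argued against by YAP1 at 15.8% and WWTR1 at 12.3% of the siCo mean. Over 354 genes that differ between the combinations without this library, its median place was 0.83 from siYAP/TAZ#1 (0) to the other siYAP/TAZ#2 libraries (1), against 0.112 or less for each siYAP/TAZ#1 library placed the same way, which argues against a swap with a siYAP/TAZ#1 library, and no biological explanation was tested.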

How the results depend on the processing

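Library size alone, offsets for GC content, TPM after TMM factors and the count without 3 sequence words were alternatives chosen after the result was seen. YAP1 and WWTR1 kept their direction and call under every alternative in which they were fitted, which leaves out the minimum fold change and the count without 3 words. Of the gene list values, 2900 either kept direction and call or were uncalled both times (95 became calls, 155 lost theirs, 0 reversed). Values uncalled both times were counted as unchanged whatever their sign, here and for genes. For the genes named, 6789 values were unchanged in that sense, 38 became calls, 276 lost theirs and 35 reversed. Over all 208 genes of the naming rule these were 9728, 57, 442 and 69. A minimum fold change leaves fewer calls by construction. So does the count without 3 words, which drops the 2744 searched genes that carry any of them. A mean count of at least 50 takes low genes out of the test, and the symbol pattern counts another set of lncRNA genes. All reversed values of named genes came with library size alone or on TPM without TMM factors. On log2(TPM + 1), 17 reversed and 104 lost their calls, against 15 lost calls on TPM after TMM factors. Beyond this the cause was not tested. Depth limits low genes, since a count of 10 was 0.25 to 0.375 CPM.

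With an absolute log2 change of at least 1 there were 317 lower and 850 higher genes with siYAP/TAZ#1, 403 and 1078 with siYAP/TAZ#2, 125 and 607 with both, 0 in opposite directions and 142 lower and 146 higher in the direct comparison. For lncRNA genes these were 27 and 146, 59 and 163, and 12 and 85, with 2 and 17 in the direct comparison. With library size alone there were 1905 lower and 5876 higher genes with siYAP/TAZ#1, 2037 and 6538 with siYAP/TAZ#2, 1134 and 4631 with both. For lncRNA genes these were 73 and 828, 127 and 838, and 53 and 556. HSPA5 with siYAP/TAZ#2 turned to 0.054 there. On log2(TPM + 1) there were 156 lower and 1736 higher genes with siYAP/TAZ#1, 198 and 3519 with siYAP/TAZ#2, 70 and 1387 with both, 1 in opposite directions and 78 lower and 39 higher in the direct comparison. For lncRNA genes these were 8 and 253, 18 and 517, and 6 and 166, with 2 and 1 in the direct comparison. On log2(TPM + 0.1) there were 172 lower and 2137 higher genes with siYAP/TAZ#1, 207 and 3860 with siYAP/TAZ#2, 69 and 1749 with both, 2 in opposite directions and 69 lower and 49 higher in the direct comparison. For lncRNA genes these were 7 and 330, 19 and 581, and 5 and 228, with 1 and 2 in the direct comparison. Both TPM settings called 3 lists in the direct comparison. TPM after TMM factors gave 59 genes in opposite directions, 826 and 896 in the direct comparison and 19 lncRNA genes lower there.

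Reversed on log2(TPM + 1) were, with siYAP/TAZ#1 RPL14 (0.094), RPL9 (0.10), MIR31HG (0.10), MIR22HG (0.15), MEG3 (0.035) and GAS5 (0.032); with siYAP/TAZ#2 ITGAV (0.33), HSPA5 (0.31), SQLE (0.079), ATP5MC1 (0.075), RPL14 (0.082), RPL9 (0.12), H3-3B (0.067), OIP5-AS1 (0.27), MIR31HG (0.15), MIR22HG (0.094) and MEG3 (0.19). On log2(TPM + 0.1) the same genes reversed, with siYAP/TAZ#1 RPL14 (0.10), RPL9 (0.10), MIR31HG (0.11), MIR22HG (0.17), MEG3 (0.035) and GAS5 (0.032); with siYAP/TAZ#2 ITGAV (0.34), HSPA5 (0.31), SQLE (0.080), ATP5MC1 (0.075), RPL14 (0.083), RPL9 (0.12), H3-3B (0.067), OIP5-AS1 (0.29), MIR31HG (0.16), MIR22HG (0.10) and MEG3 (0.19).

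By symbol pattern, lncRNA genes numbered 71, 254, 105, 266, 51 and 168 in the same order, with 53 higher in the direct comparison. At a mean count of at least 50, 95 and 144 lncRNA genes were lower and 7 lists were called in the direct comparison. Gene length offsets gave 73 opposite genes and 948 and 901 in the direct comparison (lncRNA 14 and 53). GC offsets gave 299 opposite genes, and 2519 lower and 2515 higher with siYAP/TAZ#1 than siYAP/TAZ#2 (lncRNA 55 and 151). Among genes with none of the 3 words, 59 were opposite and 881 higher in the direct comparison. An estimated correlation left 9, 11 and 0 lists, and fry called 38 with siYAP/TAZ#1. With the siCo libraries split 6 ways, 1786, 1812, 1826, 1811, 1803 and 1825 genes were higher with both, 96, 99, 110, 101, 105 and 96 opposite, and 72, 70, 66, 71, 65 and 61 lncRNA genes lower and 150, 141, 147, 151, 146 and 148 higher with both.

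Leaving out each library gave 117 to 311 opposite genes, 1278 to 2840 lower and 1178 to 2287 higher in the direct comparison, with 25 to 62 and 61 to 164 lncRNA genes. Its ranges for genes lower and higher were 3446 to 4950 and 3108 to 4224 with siYAP/TAZ#1, and 3683 to 4893 and 3704 to 4614 with siYAP/TAZ#2. The largest direct counts came without siYAP/TAZ#2 replicate 1.

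A replicate block gave 4060 lower and 3561 higher genes with siYAP/TAZ#1, 4231 and 4035 with siYAP/TAZ#2, 2928 and 2686 with both, 152 in opposite directions and 1747 lower and 1519 higher in the direct comparison, and changed no other count by over 1.5 times. Same-number pairs of libraries correlated at -0.514 to 0.67, with 5 of 12 above 0.1, and 5 of 12 libraries correlated best with their own number, so the numbers were not treated as pairs. These correlations and the GC correlations below use deviations from group means. In siYAP/TAZ#2 replicate 1 therefore also shifts the values of the other replicates, which makes the check weak for that group. The 3 pairs of replicate 4 alone correlated at 0.586, 0.587 and 0.67. Its libraries had the lowest MIR663AHG share of each group (3.83%, 2.18% and 2.45% of counts in siCo, siYAP/TAZ#1 and siYAP/TAZ#2). They also had negative GC correlations (-0.678, -0.584 and -0.638) and positive second principal components (23.6, 27.4 and 16.2). In siYAP/TAZ#2 these last values did not set replicate 4 apart. There replicates 2 and 3 had GC correlations of -0.688 and -0.617, and replicate 2 had a second component of 22.2. Whether the replicate 4 libraries were handled together was not given in the sources used here. DESeq2 gave no adjusted p for 20108, 19271 and 28483 of 43210 genes in the 3 comparisons.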

Other observations

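All tests in this part were chosen after the result was seen, and the 7-base words were first noticed over all genes before some genes were held out, so the held-out genes were not fully untouched.

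Some of the genes that differ between the combinations share short words in the 3' UTR, with 32.6% of GGAACTT carriers called lower with siYAP/TAZ#1 (11.9% of other genes) and 34.8% of CTTCTTA carriers higher (8.36%). Among held-out genes, 595 carriers of GGAACTT were lower with siYAP/TAZ#1 than siYAP/TAZ#2 by -0.20 ± 0.018 against the other genes, and 735 carriers of CTTCTTA higher by 0.20 ± 0.018. GGAACTT went with siYAP/TAZ#1 (-0.22 and -0.019 against siCo) and CTTCTTA with siYAP/TAZ#2 (0.013 and -0.19); the largest value for another word of the same bases was -0.13 and 0.051, against base composition, and for the words outside the 3' UTR -0.090 and 0.029. GGAACTT lies in WWTR1 and CTTCTTA in YAP1 and WWTR1, which is weak evidence since 34.2% and 58.7% of words of the same bases lie in these transcripts; siRNA seed matches may add to the difference between the combinations, but the siRNA sequences were not in the labels and this remains a hypothesis. GACTAAT carriers were higher with both by 0.11 ± 0.024, but 1 of 417 words of the same bases did as much, so a control siRNA seed match cannot be told apart from that.

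The share of lncRNA genes that rose among those called with both combinations was 74.7%. Equally abundant coding genes rose in 81.6%, so low abundance could account for it. The share was 74.3% among lncRNA genes outside coding genes and 75.1% among those overlapping them. That argues against reads of overlapping coding genes as its source. Neither share lay above the 81.6% of equally abundant coding genes. With GC offsets the lncRNA share was 75.1%. Coding genes were not recounted with these offsets, so GC content bias cannot be judged against genes of equal abundance. A regulation of lncRNA genes as a class was not tested.

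Other splits of the libraries were counted for comparison. Each of them mixes treatments within a group, which raises the spread there, so low counts were fixed largely in advance. They therefore cannot exclude chance. For counts of genes the real split was the only 1 as large. With 8 libraries and 35 splits, genes called numbered 8925 with siYAP/TAZ#1 (highest other 0), 7315 with siYAP/TAZ#2 (highest other 2) and 2671 between them (highest other 133). For lncRNA genes the counts were 739, 594 and 101 (highest others 0, 2 and 23). Among 100 splits the counts were 5560 for genes called alike with both (highest other 1), 149 in opposite directions (highest other 0) and 396 for lncRNA genes alike (highest other 0). For gene lists at the preset correlation even these splits did as much, so chance stays open. With 25, 26 and 14 lists, 2, 3 and 4 of 35 splits gave as many, the real split included. The highest others were 26, 27 and 18. With an estimated correlation the real groups gave 8 and 10 lists against siCo (highest other 0).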
